A study of Mus musculus with 12 samples.

How the data were processed

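RNA was measured by bulk sequencing of snap-frozen heart ventricle from 12 C57BL/6J offspring, per the labels' protocols: 6 sired by males that had received a cardiac cryoinjury on postnatal day 1 and 6 sired by uninjured males. The labels gave 3 males and 3 females in the injured-sire group and 4 males and 2 females in the uninjured-sire group, without saying which animal was which, and gave no sire, litter, collection time or sequencing batch per animal. The deposited file holds raw read counts per Ensembl gene, with no normalization, made with featureCounts 2.1.1 with the strand setting 2 (reverse), without the paired-end option and without counting multi-mapping reads, on the Ensembl release 114 annotation of GRCm39, per the file headers. The submitters' processing notes name Subread 2.0.3, STAR 2.7.10a, Salmon 1.9.0, DESeq2 1.44.0, R 4.4.0, FastQC 0.11.9 and MultiQC 1.12, and the Subread version there differs from the featureCounts version in the file header. Since reads that map to several places were not counted, genes with near-identical copies, such as mt-Co2 and mt-Co3, are uncertain. Another 11 sample columns of the table belong to no sample described here and were not used in any step. Of 78317 gene IDs, 51487 were matched without version numbers to symbols of GENCODE release M21, and these took 99.3% of counts. That release is on another genome build, so it served for names only, and coordinates are those of the counted file.

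Totals per library ran from 30537315 to 42090257 counts. Replicate numbers come from the sample titles and no number occurs in both groups. All pairs of libraries within a group differed by far more than counting noise (chi-square per degree of freedom of 14.5 to 45.9 over 30 pairs), so none was treated as a repeat of another. The comparison used 5 injured-sire and 6 uninjured-sire libraries, without replicate 16, which the labels name as an outlier in a principal component analysis. In R 4.3.3, edgeR 4.0.16 was used with filterByExpr (minimum count 10, minimum total 15), TMM factors and the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, on 17130 genes. SEs come from the F statistic and confidence intervals are at 95%. CPM are counts scaled to a library size of 1e6 after TMM scaling, and log2 CPM carry a prior count of 2. The median half-width of a gene's confidence interval was 0.262 on the log2 scale.

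Before the data were examined, 42 gene lists, the tests, the naming rule and most alternatives were fixed. Lists with at least 5 measured genes, 40 in all without the sex-linked list, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry (a directional test of the list alone). The exact permutation of list scores, added after the data had been seen, compared the list's mean centred log2 CPM per library over 462 splits. At 462 splits even the smallest possible p of a list does not pass by itself after adjustment over 40 lists. The naming rule took, from genes past the threshold with an average log2 CPM of at least 0 and a symbol that is not a predicted or clone name and not sex-linked, the 12 with the largest rise and the 12 with the largest fall, then the 3 members of each list with the smallest p, and Nppa, Nppb, Myh6, Myh7, Col1a1, Mki67, Il1b, Igf2, Ucp1 and Xist. Extra genes below the threshold, 8 in each direction, were to be added if fewer than 12 genes passed, which did not apply. Values of some genes that this rule or a later choice took are not reported here. Single values per library were compared by exact permutation tests. The chain of steps was tested on simulated counts for the 17130 genes of this comparison, with 200 genes changed: the test called 5 of 50 genes changed by 1.25-fold, 23 of 50 by 1.5-fold, 34 of 50 by 2-fold and 42 of 50 by 3-fold, with 6 false calls among 110. Small changes of the size seen here are therefore mostly missed at this number of animals.

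Alternatives fixed beforehand were all 12 libraries, each library left out in turn, DESeq2 1.42.0 size factors, no scaling factor, upper-quartile factors, the DESeq2 Wald test, limma voom with sample quality weights, no filter, a filter of 1 CPM in 5 libraries, a continuous sex-linked covariate, 1 surrogate variable from sva 3.50.0, no mitochondrial genes, a threshold of 0.1, a test against a 1.2-fold change, and variance-stabilised values of the 500 most variable genes for the comparison of libraries. A clock score, airway and fat scores as covariates, and the exact permutation of list scores were added after the data had been seen. The clock score was the mean of Per1, Per2, Per3, Dbp, Tef, Hlf, Ciart, Nr1d2 and Bhlhe41 minus the mean of Arntl, Npas2 and Clock in log2 CPM, and these genes were also chosen with the clock values in view. The DESeq2 Wald test gave no adjusted p for 2326 genes, and these were left out of its comparison of calls. A change of sign counted as a reversal where the value was called in either setting.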

Results

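The deposited table held read counts per gene for 12 heart ventricle libraries from C57BL/6J mice, 6 from offspring of males whose hearts had been injured by freezing (cryoinjury) on postnatal day 1 and 6 from offspring of uninjured males. The offspring themselves were not injured. Collection was labelled 3 wpp, although the same label called the animals adult, and both statements are given here as they stand. The comparison asks whether a father's neonatal heart injury goes with a difference in the hearts of its offspring. Replicate 16 of the injured-sire group was left out of the comparison, as in the submitters' own downstream analysis, so 5 libraries were set against 6. Totals ran from 30537315 to 42090257 counts per library. The labels do not say which sires or litters the animals came from, so p-values measure the spread between these animals, and siblings would make them too small.

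Hearts of offspring of injured males differed from those of uninjured males in a small set of genes, most of them by less than 2-fold. Of 17130 genes tested, 9 were higher and 9 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The genes that rose included Usp2, a ubiquitin-specific protease, Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, Fzd4, a Frizzled receptor, and Bmp10, a cardiac bone morphogenetic protein. The genes that fell included Dhrs3, a retinaldehyde reductase, Npas2, a clock transcription factor that pairs with Arntl, and Kcnj2, an inward-rectifier potassium channel. Of the 15 genes that the naming rule took from these 18, 13 changed by less than 2-fold.

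Among the genes that rose, Usp2 (chromosome 9, 43978318 to 44006924, GRCm39) went from 130 ± 13.8 CPM (SD, n = 6) in offspring of uninjured males to 184 ± 13.8 CPM (SD, n = 5), a log2 fold change of 0.50 ± 0.0689 (SE, edgeR adjusted p = 0.0016). Nfkbia (chromosome 12, 55536195 to 55539432) rose by 0.49 ± 0.0776 on the log2 scale, from 75.3 ± 8.29 to 105 ± 11.4 CPM (edgeR adjusted p = 0.0107). Rbm3, a cold-inducible RNA-binding protein gene (chromosome X, 8005214 to 8012119), rose by 0.40, and its groups overlapped. Fzd4 (chromosome 7, 89053563 to 89062342) rose by 0.37 and Bmp10 (chromosome 6, 87405976 to 87414659) by 0.29, from 234 ± 13.5 to 287 ± 14.2 CPM. Slc12a4, a potassium-chloride cotransporter gene (chromosome 8, 106670222 to 106692729), rose by 0.28. The edgeR adjusted p of Rbm3 and Slc12a4 was 0.0484 for both.

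Among the genes that fell, Dhrs3 (chromosome 4, 144619397 to 144654779) had the smallest p of all genes tested. It went from 79.6 ± 4.74 CPM (SD, n = 6) to 55.5 ± 2.35 CPM (SD, n = 5), a log2 fold change of -0.52 ± 0.0572 (SE, edgeR adjusted p = 0.000126). Npas2 (chromosome 1, 39232812 to 39402317) fell by 1.05 on the log2 scale, from 9.67 ± 1.38 to 4.68 ± 1.37 CPM (edgeR adjusted p = 0.00998). Adam19, a membrane metalloprotease gene (chromosome 11, 45946819 to 46038170), fell by 0.53, Ifi203, an interferon-inducible gene (chromosome 1, 173747973 to 173770238), by 0.50, Tmem140 (chromosome 6, 34840081 to 34851881) by 0.40 and Kcnj2 (chromosome 11, 110956990 to 110967647) by 0.37. Both called mitochondrial genes encode RNAs that are not translated: mt-Ti, a transfer RNA gene, changed by -0.58 ± 0.0873 and mt-Rnr1, the small ribosomal RNA gene, by -0.43 ± 0.0700. The protein-coding genes of the mitochondrial genome were not called as a list.

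**Figure D1:**
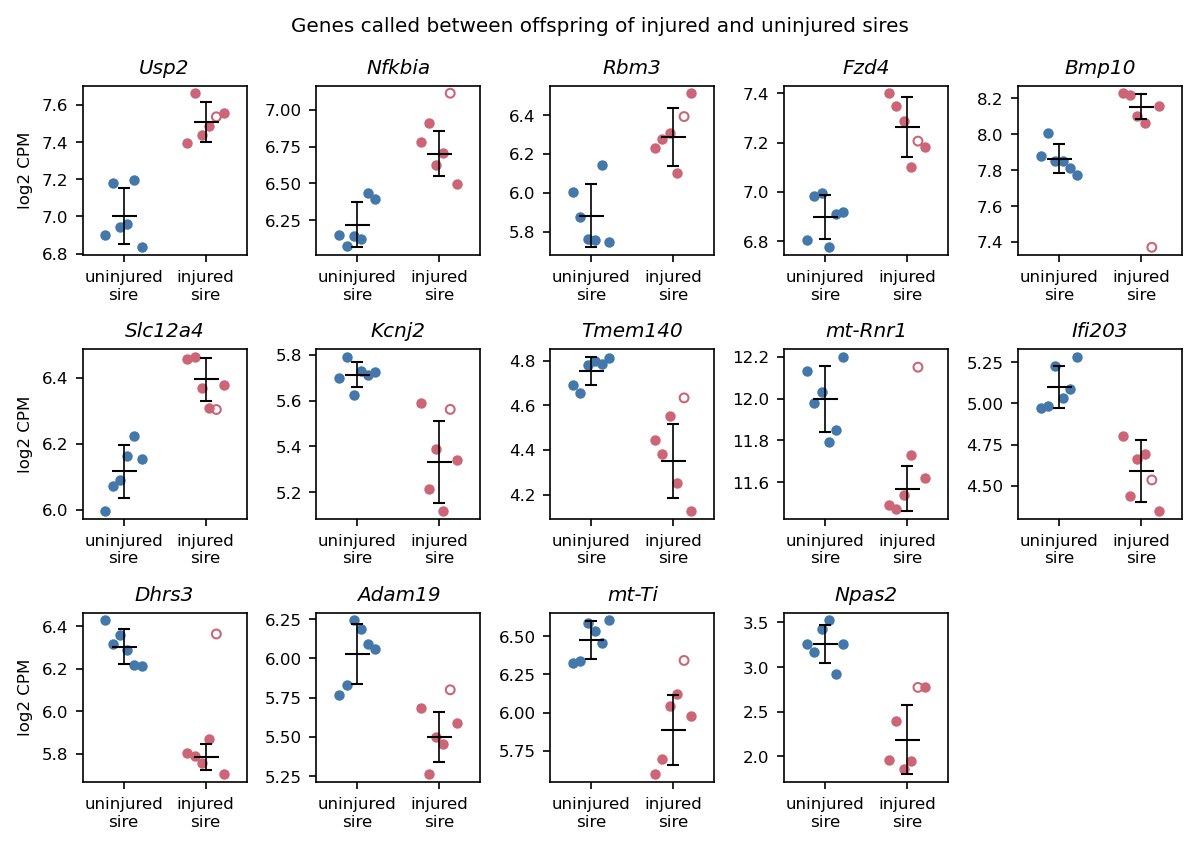
Log2 CPM (counts scaled to library size) of 14 named genes that passed the test, one point per library, with the mean and SD of the libraries compared (6 of uninjured and 5 of injured sires). Open circles show replicate 16 of the injured-sire group, which was left out of the comparison and lay far from its group for Bmp10 (7.37) and Dhrs3 (6.36); each panel has its own axis.

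The other 3 called genes fall outside the naming rule and were picked out after their values were seen. ENSMUSG00000137768 (chromosome 14, 55232295 to 55250671, plus strand) rose by 0.62 ± 0.0767 on the log2 scale (edgeR adjusted p = 0.000529). It starts 212 bp from the start of Myh7, the slow myosin heavy chain gene, which runs the other way on the opposite strand, whose own log2 fold change was -0.03 ± 0.265. Gm29676 (chromosome 13, 44254445 to 44471196, minus strand) rose from 1.11 ± 0.523 to 3.55 ± 0.488 CPM. ENSMUSG00000130840 (chromosome 14, 54490988 to 54491545, plus strand) had 11 to 24 counts in the 6 injured-sire libraries, replicate 16 among them, and 0 to 2 in the uninjured-sire libraries. Its fitted log2 fold change of 4.19 ± 0.779 rests on those few counts. The whole 558 bp of the gene lie within the span of Dad1 on the opposite strand, 100 bp from the start of Abhd4, and neither Dad1 (0.08) nor Abhd4 (0.03) passed the test. Counting was by strand, per the file header.

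The number of calls depended on single libraries: 28 without injured-sire replicate 12, 8 without 13, 9 without 14, 43 without uninjured-sire replicate 22 and 9 without 23. With replicate 16 included 14 genes were called, 10 of them shared with the 18, and Dhrs3, Bmp10, Kcnj2, Slc12a4, Tmem140, mt-Ti, mt-Rnr1 and ENSMUSG00000137768 no longer passed. With a covariate for sex-linked genes 14 genes were called, 13 of them shared with the 18, and Rbm3, Bmp10, Tmem140 and Slc12a4 were among those lost. With a surrogate variable 17 genes were called, 13 higher and 4 lower, and only 6 of the 18 were among them. With airway and fat scores as covariates, an alternative chosen after seeing the data, 20 were called, 16 higher and 4 lower, with 7 of the 18 among them. Scaling moved the split of calls from 9 higher and 9 lower to 17 and 8 with no scaling factor, and to 7 and 12 with upper-quartile factors.

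Clock genes were the list with the most members past the threshold when each list was adjusted alone, though over all genes only 1 passed. Of 18 measured core clock genes and direct outputs, Npas2 was called over all genes, and 12 passed when adjusted over the list alone, 8 higher and 4 lower. Genes that repress the cycle or follow it were higher in offspring of injured males: Ciart by 1.58 ± 0.305 (log2, SE), Per2 by 0.90 ± 0.217, Per3 by 0.72, Per1 by 0.61, Tef by 0.51, Hlf by 0.49, Bhlhe40 by 0.38 and Cry2 by 0.25. The activators Arntl (-1.13 ± 0.388), Npas2 and Clock (-0.25), and the repressor Nr1d1 (-0.24), were lower. As a list the clock genes were called higher by camera (adjusted p = 0.0188), with adjusted p = 0.592 with an estimated correlation, although their members went both ways. Without injured-sire replicate 13 the list was not called. Uninjured-sire replicate 22 had Arntl at 2.99 log2 CPM, against 3.90 to 4.34 in the rest of its group, and injured-sire replicate 17 had 3.92. Among the members beyond the first 3 by p, names were chosen after the values were seen. With a clock score as a covariate, an alternative chosen after seeing the data, no gene passed the edgeR test, and 937 genes had an unadjusted p below 0.05.

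**Figure D2:**
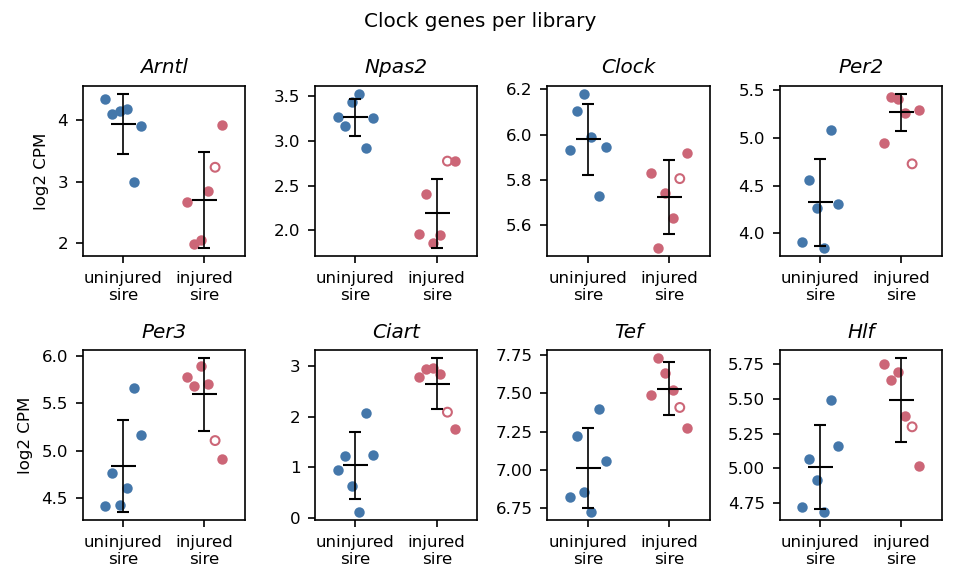
Log2 CPM (counts scaled to library size) of 8 clock genes, one point per library, with the mean and SD of the libraries compared (6 of uninjured and 5 of injured sires); the open circle is replicate 16, which was left out. Arntl, Npas2 and Clock lay lower and Per2, Per3, Ciart, Tef and Hlf higher in offspring of injured sires, and among these genes only Npas2 passed over all genes; each panel has its own axis.

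Interferon-stimulated genes were lower in offspring of injured males. Of 35 measured members, 30 were lower, with a median log2 fold change of -0.19, and camera called the list (adjusted p = 6.02e-07; adjusted p = 0.236 with an estimated correlation). No member was called over all genes, and 4 passed when adjusted over the list alone: the guanylate-binding protein genes Gbp2 (-0.44 ± 0.0901) and Gbp7 (-0.41 ± 0.0832), the antiviral gene Rsad2 (-0.37 ± 0.0791) and the signalling gene Stat2 (-0.24 ± 0.0769). Gbp2 and Gbp7 just missed the threshold over all genes, each with an edgeR adjusted p of 0.0516. The direction also passed in fry (adjusted p = 0.0332). The mean of the list per library had an exact two-sided permutation p of 0.00433, or 0.173 after adjustment over 40 lists.

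Of 24 macrophage markers measured, 21 were lower (median -0.22), and camera called the list (adjusted p = 0.00736; adjusted p = 0.749 with an estimated correlation). Adjusted over the list alone, 3 passed, against 0 over all genes in edgeR: the Fc receptor gene Fcgr1 (-1.05 ± 0.312), the fractalkine receptor gene Cx3cr1 (-0.71 ± 0.200) and the complement gene C1qa (-0.24 ± 0.0734). Of the 6 with an unadjusted p below 0.05 in edgeR, Mertk was higher (0.34 ± 0.121). Csf1r (-0.07 ± 0.0941), Cd163 (-0.05 ± 0.197) and Mrc1 (0.0008 ± 0.0999) were among the members that changed little. Fcgr1 lay at 0.988 against 2.05 CPM. The list was not called without injured-sire replicate 17 or without uninjured-sire replicate 22.

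**Figure D3:**
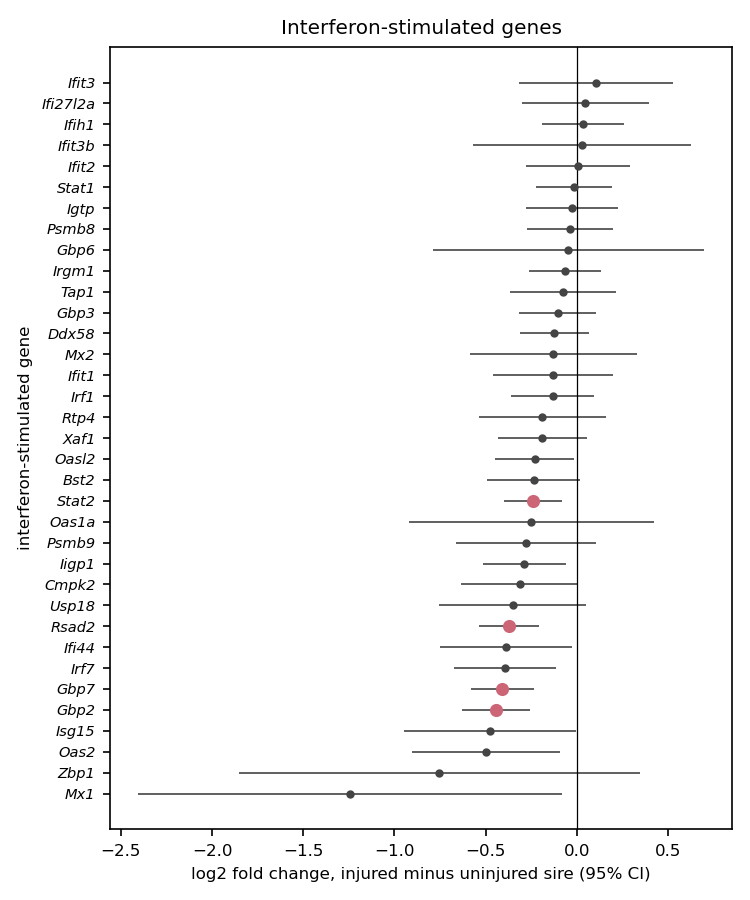
Log2 fold change of 35 interferon-stimulated genes, offspring of injured minus offspring of uninjured sires, with 95% confidence intervals from edgeR. Of these, 30 lie below 0; the 4 larger points are Gbp2, Gbp7, Rsad2 and Stat2, which passed when adjusted over the list alone.

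Another 4 lists were called higher, and each had its call lost with an estimated correlation. Fat markers were higher in 14 of 15 members (median 0.55, camera adjusted p = 0.000252; adjusted p = 0.749 with an estimated correlation), yet no member passed over the list alone, and Ucp1, the brown fat uncoupler, was at 115 ± 66.0 CPM (SD, n = 5) against 67.0 ± 53.7 CPM (SD, n = 6). Sterol and fatty acid synthesis genes were higher in 18 of 22 (median 0.11, camera adjusted p = 0.00208; adjusted p = 0.592 with an estimated correlation). Smooth muscle and pericyte markers were higher in 12 of 17 (median 0.13, camera adjusted p = 0.0188; adjusted p = 0.592 with an estimated correlation): adjusted over the list alone, Acta2 (0.38 ± 0.0954) and Mylk (0.27 ± 0.0864) were higher and Vtn lower (-0.27 ± 0.0851). Neutrophil markers were higher in 10 of 10 (median 0.53, camera adjusted p = 0.0188; adjusted p = 0.749 with an estimated correlation), at low levels such as 0.844 against 0.291 CPM for Ngp. The smooth muscle list was not called without injured-sire replicate 12, nor the neutrophil list without injured-sire replicate 13 or 15 or uninjured-sire replicate 19 or 20.

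The fat, sterol, smooth muscle and neutrophil lists were not called once airway and fat scores were covariates, an alternative chosen after seeing the data. Airway signal was unevenly spread between the libraries compared: the secretory gene Scgb1a1 had a median of 3313 counts in the 5 injured-sire libraries (627 to 10427) and 34.5 in the 6 uninjured-sire libraries (8 to 5574), and replicate 16, left out, had 8. The fitted difference was not called (log2 fold change 1.41 ± 1.53, SE, edgeR adjusted p = 0.857). Of 100 splits of the 11 libraries into 5 and 6, 61 gave at least the 7 called lists of the real split, and with an estimated correlation camera called 0 of 40 lists, with 1 at an unadjusted p below 0.05, while fry called 1.

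Genes of the contractile apparatus and of energy supply showed no called shift in the comparison of 5 with 6 libraries. This depended on the setting. The respiratory chain list was called higher with replicate 16 included (camera adjusted p = 0.0379) and lower with airway and fat scores as covariates (0.0199). The mitochondrial-genome list was called lower without uninjured-sire replicate 21 (0.00653), with a mean log2 fold change of -0.774. In the comparison of 5 with 6 libraries, mt-Co2 (-5.00 ± 1.89) and mt-Co3 (-0.67 ± 2.09), both uncertain, stood apart from its other members, at -0.14 to -0.03. That call therefore does not show a fall of these genes as a group. With the clock covariate, like the airway and fat scores chosen after seeing the data, the respiratory chain (5.56e-05), sarcomere (0.00644), calcium-handling (0.0473), glycolysis (0.00305) and citric acid cycle lists (0.0026) were called higher. Higher values were seen for 8 of 20 sarcomere genes (camera adjusted p = 0.824), 9 of 16 calcium-handling genes (0.585), 7 of 15 fetal-programme genes (0.63), 10 of 20 ion channel genes (0.412) and 10 of 13 atrial genes (0.177). Bmp10 was the only atrial member called, and Kcnj2 the only ion channel member. Nuclear respiratory chain genes were higher in 15 of 36 (0.724), mitochondrial-genome genes in 0 of 9 (0.171), fatty acid oxidation genes in 20 of 32 (0.724), glycolysis genes in 10 of 20 (0.796) and citric acid cycle genes in 12 of 16 (0.635). The natriuretic peptide genes Nppa (0.06 ± 0.0540) and Nppb (-0.11 ± 0.259), the myosin genes Myh6 (0.11 ± 0.0595) and Myh7, the collagen gene Col1a1 (0.18 ± 0.0698), the proliferation gene Mki67 (0.07 ± 0.208), Igf2 (0.24 ± 0.202), Ucp1 (0.78 ± 0.849), Il1b (0.02 ± 0.871) and Xist (0.85 ± 1.96) were not called.

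Markers of other cell types and states were not called either. Members were higher in 12 of 20 for fibroblast (camera adjusted p = 0.558), 25 of 33 for matrix and fibrosis (0.143), 12 of 22 for endothelial (0.386), 1 of 7 for lymphatic (0.635), 9 of 11 for epicardial and mesothelial (0.0791), 7 of 8 for endocardial (0.386), 10 of 11 for glial and neuronal (0.122), 2 of 15 for lymphoid (0.386), 3 of 11 for erythroid (0.335) and 10 of 11 for skeletal muscle, lung and liver genes (0.167). For states the counts were 22 of 35 for cell cycle (0.356), 12 of 24 for cytokine and NF-kB genes (0.635), 5 of 15 for complement and acute phase (0.796), 12 of 25 for immediate early (0.758), 13 of 31 for heat shock and unfolded protein response (0.724), 11 of 15 for glucocorticoid (0.171), 12 of 19 for hypoxia (0.335) and 9 of 22 for oxidative stress genes (0.724). The remaining counts were 18 of 37 for ribosomal proteins (0.7), 22 of 40 for imprinted genes (0.909), 16 of 34 for chromatin modifiers (0.724), 16 of 28 for growth, IGF and Hippo genes (0.909) and 13 of 23 for renin, natriuretic and adrenergic genes (0.463). In 9 of these uncalled lists the median, the mean and the test differed in sign: fetal programme, ribosomal proteins, chromatin modifiers, fatty acid oxidation, oxidative stress, immediate early, complement, cytokine and growth lists. Some of these lists were called in other settings: the epicardial list higher in 7 of them, and the glucocorticoid list higher in 4, among them with replicate 16 included (camera adjusted p = 0.0129). Without 1 uninjured-sire library, the glial list (0.0304, without 18) and the matrix list (0.0149, without 19) were called higher and the erythroid list lower (0.0181, without 23). The skeletal muscle, lung and liver list was called higher with no filter (0.00325), and ribosomal proteins higher with replicate 16 included (0.0116). Covariates chosen after seeing the data added further calls: with the clock score, cell cycle (9.73e-07) and ribosomal proteins (0.023) higher and cytokine (0.013) and complement genes (0.0473) lower, and with airway and fat scores, lymphoid (0.00393) and ribosomal protein genes (0.0364) lower. Thymus markers had 3 measured members, too few for the test, with 1 higher, and of 5 sex-linked genes, kept out of the test, 1 was higher.

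The mitochondrial genome took 17.7 ± 0.776% of counts (SD, n = 5) in offspring of injured and 18.5 ± 1.09% (SD, n = 6) in offspring of uninjured males, a difference below the threshold (exact two-sided permutation p = 0.201) that passed it without uninjured-sire replicate 21 (p = 0.00794, exact). Fewer genes had at least 1 count in the injured-sire libraries, 22970 ± 803 against 25090 ± 1070 (exact permutation p = 0.00866, adjusted p = 0.0433 over 5 library measures), while total counts showed no difference past the threshold (exact permutation p = 0.887). Whether this difference between the libraries bears on the called genes was not tested. Y-linked expression was found in 3 injured-sire and 4 uninjured-sire libraries, the numbers of males in the labels, so the sexes were not balanced between the groups. These counts cover all 12 libraries, replicate 16 among them, so the balance among the 11 libraries compared is a different one. Replicate 16 stood apart from its own group more than from all libraries. By chi-square per degree of freedom its 5 pairs with its group were the most distant of the 30 pairs within groups, at 34.7 to 45.9 against at most 31.1 for the others. On the first principal component (21.5% of the variance) it lay at 30.7, outside the -44.7 to 8.83 of its group and within the -24.3 to 44.6 of the uninjured-sire group. It had the highest mitochondrial share of all libraries (20.1%), the highest share in the 10 most abundant genes (25.5%) and the lowest TMM factor (0.927), while its mean rank correlation with all other libraries ranked 7 from the lowest of 12.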

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

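The tests of clock phase and of a wrong label below, and the covariates for airway and fat, were chosen after the results had been seen. Within the groups of 6, 148 sets of values were searched for a library far from its group, and 8 such values were found, where chance gives about 1 in 20.

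Replicate 16 of the injured-sire group, left out of the comparison, lay far from its group for 3 called genes: Bmp10 at 7.37 log2 CPM (others 8.06 to 8.23), Dhrs3 at 6.36 (others 5.70 to 5.87) and ENSMUSG00000137768 at 5.03 (others 5.71 to 6.03). These genes were called without replicate 16, which favours genes on which the other 5 libraries lie close together. The chance rate above therefore does not hold for these 3 values. Replicate 16 also held signal above every uninjured-sire library for 6 of the 9 genes that rose: Usp2 at 7.54 log2 CPM (uninjured-sire libraries up to 7.20), Nfkbia at 7.11 (up to 6.44), Rbm3 at 6.39 (up to 6.14), Fzd4 at 7.21, Slc12a4 at 6.30 (up to 6.22) and ENSMUSG00000130840 at -1.13 (up to -3.29). The 9 genes that fell were not counted in this way. Over all 18 genes it lay on its own group's side for only 8.

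Replicate 16 stood between the groups: it lay nearer to its own group's mean for 8 of the 18 called genes, or 44.4%. When each of the other libraries was left out in turn, that share had a median of 73.7% and a lowest value of 41.9%, for uninjured-sire replicate 22. The first threshold for a wrong label was that lowest value, which replicate 16 exceeded, and it was replaced by the median after the result had been seen, because a margin this small lies within the spread of the other libraries. Under the first threshold the result argued against a wrong label, and under the median neither side was reached. A wrong label and a true difference of this animal therefore could not be told apart at 44.4%. Its airway score, -4.36, was the lowest of all libraries. The rest of its group had 0.37 to 4.23, and the uninjured-sire group -4.22 to 3.3. Its score for the atrial list, which holds Bmp10, was also the lowest, at -0.281 (other libraries -0.104 to 0.143). Admixed or atrial tissue as a source of its place between the groups was not tested and stays open too.

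In the uninjured-sire group, replicate 22 had Arntl at 2.99 log2 CPM (others 3.90 to 4.34).

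Of 18 clock genes, Npas2 was called over all genes and 12 passed over the list alone, but the list as a whole was not called with an estimated correlation (adjusted p = 0.592), with fry or with the exact permutation of its scores. The Per and Dbp arm was higher by 0.691 and the Arntl arm lower (-0.858), a difference of 1.55 (exact permutation p = 0.0108), but the arms were drawn up with the clock values in view and leave out genes such as Nr1d1, Cry1, Cry2, Bhlhe40 and Nfil3, of which Nr1d1 was lower (-0.24), against its arm, so this p is largely fixed by the choice and is no independent evidence. With airway and fat scores as covariates the same difference stayed at 1.6 ± 0.548 (SE), against 1.55 ± 0.389 without them, so these scores did not remove it. They are means of markers that measure admixed tissue imperfectly. The scores also differed between the groups, by 4.06 for airway and 1.15 for fat, so this fit cannot exclude admixed tissue. A different time of collection may underlie the difference of 1.55, but an effect of the sire on the clock predicts the same. Both stay open, since the labels give no collection times.

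With the clock score as a covariate no gene was called. The 18 called genes kept a median of 93.1% of their log2 fold change, all 18 with the same sign and 17 with an unadjusted p below 0.05 in edgeR, while the median SE grew from 0.0781 to 0.128. The calls ended through the larger SE. The clock score overlapped with the groups, with a variance inflation (growth in the variance of the group term from that overlap) of 2.76. Npas2 is also itself part of the score. This fit therefore cannot separate the clock from the sire, and the share kept does not show that these genes change apart from the clock.

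Uninjured-sire replicate 21 had ENSMUSG00000137768 at 5.49 log2 CPM (others 5.10 to 5.23) and 16.4% of counts from the mitochondrial genome (others 18.5 to 19.4%). Uninjured-sire replicate 20 had Ucp1 at 0.925 log2 CPM (others 4.92 to 7.04). Injured-sire replicate 12 had Il1b at -1.79 log2 CPM (others 0.653 to 1.03).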

How the results depend on the processing

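The clock covariate, the airway and fat covariates and the exact permutation of list scores were chosen after the data had been seen. Against 18 called genes, counts were 236 without a filter on low counts, 28 with at least 1 CPM in 5 libraries, 134 with the DESeq2 Wald test (17 shared with the 18) and 49 at a threshold of 0.1. With a surrogate variable 17 were called but only 6 of the 18, and with airway and fat covariates 20 but only 7 of the 18. They were 0 against a 1.2-fold change (413 at an unadjusted p below 0.05) and 0 with the clock covariate (937 below 0.05). Leaving out 1 library gave 8 (without injured-sire replicate 13) to 43 genes (without uninjured-sire replicate 22). Against 7 called lists, counts were 4 with a surrogate variable, 14 with the clock covariate, 1 with fry, 0 with an estimated correlation and 0 with the exact permutation, where 6 had an unadjusted p below 0.05. The mitochondrial share differed by -1.21 to -0.485 percentage points when 1 library was left out, past the threshold only without uninjured-sire replicate 21. Replicate 16 ranked 10 from the lowest on variance-stabilised values. List means that changed sign and were called in either setting were nuclear respiratory chain with all 12 libraries (0.0465). With the clock covariate they were sarcomere (0.0762), nuclear respiratory chain (0.0888), glycolysis (0.118), complement (-0.243) and the clock list itself (-0.0247). With airway and fat covariates they were fat (-0.0392) and ribosomal proteins (-0.0639). A covariate built from clock or fat genes removes its own list by construction, and for the other changes the cause was not tested. In the 24 settings tested gene by gene, which leave out the 0.1 threshold and the 1.2-fold test (none of the 18 passed the latter), Npas2, Usp2 and Gm29676 were called in 23 and lost with the clock covariate, and the interferon list was called in 24 of 26. Tmem140 and Slc12a4 were called in 7 of 24. Over these settings the 18 genes kept their call in 298 of 428 cases and lost it in 130, other named genes were newly called in 69 cases, and none changed sign with a call.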

Other observations

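The covariates for the interferon genes below were chosen after that list's result had been seen. The following members of lists that were not called passed when adjusted over their list alone and not over all genes. Vascular genes among them were Rgcc (0.50 ± 0.101, log2, SE), a complement-response cell cycle regulator found in endothelium, and Vwf, the von Willebrand factor gene (0.29 ± 0.0669), although 12 of 22 endothelial markers were higher and the list was not called. Adrenergic and natriuretic signalling had the phosphodiesterase gene Pde4d (0.38 ± 0.103) and the natriuretic peptide clearance receptor gene Npr3 (0.28 ± 0.0779) higher, and the receptor kinase gene Grk5 lower (-0.32 ± 0.0861). Among stress-hormone responsive genes Errfi1 (0.58 ± 0.175), Ddit4 (0.42 ± 0.117) and Per1 were higher and Angptl4 (-0.88 ± 0.280) was lower. Lower values were also found for Ucp3 (-0.29 ± 0.0724) in the fatty acid list, the cartilage matrix gene Comp (-0.49 ± 0.130), Asb4 in the imprinted list (-0.56 ± 0.138) and the histone deacetylase gene Hdac9 (-0.35 ± 0.0900). These genes were named because they passed, after their values had been seen.

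The skeletal muscle troponin gene Tnnt3 was higher by 1.38 ± 0.392 and passed over its list alone. Among the libraries compared, the airway gene Bpifa1 had a median of 935 counts in injured-sire (92 to 3631) and 19 in uninjured-sire libraries (0 to 2240). Counts of mt-Co3 were 1520 in injured-sire replicate 12, 3950 in 17, 5456 in uninjured-sire replicate 18 and 4769 in 19, and 0 to 25 in the other libraries.

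The 18 called genes exceeded what other splits of the same libraries gave. Of 100 splits of the 11 libraries into 5 and 6, the real one included, only the real one gave as many. The highest other count was 2. Replicate 16, nearer to the uninjured-sire mean for 10 of the 18 genes, had been left out beforehand. No other split had a library left out to match, and splits of all 12 libraries were not run. The splits also treat the animals as independent, and the labels give no sire or litter. A chance difference between litters or sires would set the real split apart as well, and the splits cannot exclude it. Chance alone is thus an unlikely source of the gene count only with these 11 libraries taken as given and as independent animals. By genes with an unadjusted p below 0.05 the real split had 1534, and 2 of 100 splits had as many, the highest other having 1544. The 7 called lists did not exceed what other splits gave. As many were found in 61 of 100 splits, with a highest other count of 15. The list count is therefore no more than chance may give.

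The lower interferon genes were weighed as 1 pattern, a difference of -0.26 ± 0.0587 (SE) in the list's mean log2 CPM. Fewer macrophages would remove it once the macrophage score is a covariate, and it stayed at -0.193 ± 0.0456, or 74.2% of its size. A different clock phase at collection would remove it once the clock score is a covariate, and it stayed at -0.384 ± 0.0875. Neither score removed the difference, and part of it may follow the macrophage score. The macrophage score is a mean of markers, some at low levels, and measures these cells imperfectly. The clock score was drawn up with the values in view and itself differed by 1.55 between the groups. These covariates therefore cannot exclude either as the whole source. Chance stays open too, with an exact permutation p for the list of 0.173 after adjustment over 40 lists. An effect of the sire, and a difference in infection or housing that the labels do not record, stay open and untested.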
